A study of Danio rerio with 6 samples.

How the data were processed

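The series holds 6 RNA-seq libraries of polyadenylated RNA from livers of adult zebrafish (Danio rerio), 3 from WT fish and 3 from lf:Yap transgenic fish. Per the labels' protocols, livers were dissected, flash frozen and extracted with Trizol and a column kit, and libraries were prepared by standard Illumina protocols. Per the submitters' processing notes, STAR 2.3.0e and HTSeq 0.6.0 were used. The genome build, the annotation, the strandedness of the libraries and the read length are not given in the sources used here. The deposited table holds raw counts, whole numbers of reads per Ensembl gene for each library, which the authors had not normalized as far as the values show. All of its 25640 genes sum to at least 30 reads over the 6 libraries. Groups and replicate numbers were taken from the sample titles. The labels do not say whether each library is 1 fish, so p-values measure the spread between these samples, which may in part be technical.

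Gene symbols came from a table of gene IDs and symbols, which matched 17999 of the 25640 IDs. Of these symbols 9671 are in human-style capitals without the letter that tells zebrafish paralogs apart, so a gene ID is given with each named gene. Entries of a gene list were matched to a symbol regardless of case and otherwise to the capital symbol of their family. With the human-style symbols, 2 or more IDs can share a symbol. The pattern for proteasome genes also took PSMC3IP, which is no proteasome subunit. A table of RefSeq genes of assembly GRCz12tu was used only for the order of genes, and no coordinates are given.

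Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group kept 24674 genes and removed 966, TMM factors were computed (1.019 to 1.108 in WT, 0.939 to 0.965 in lf:Yap), and dispersions and quasi-likelihood fits used robust estimation. The test was two-sided with Benjamini-Hochberg adjustment at 0.05. CPM were computed from the counts with TMM-scaled library sizes, and a pseudocount of 2 was used only for log2 CPM in principal components and correlations. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 44.9%, and 2791 genes had an unadjusted p under 0.05. The smallest p an exact permutation of 3 against 3 libraries can give is 0.1, so single values were not tested that way. Pairs of replicates differed far beyond sampling noise, with a chi-square per degree of freedom of 209 to 369, so no library was counted as a repeat of another. Total counts of 71581315 to 87543545 per library leave counting error small against the spread between libraries for genes above 1 CPM.

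The procedure was tested on data simulated for lf:Yap against WT, with 24046 genes tested. These data used the means over all libraries, the library sizes and the gene-wise dispersions of the real data. The 200 genes changed were drawn from those with a mean above 1 CPM, so recovery below that was not measured. The procedure recovered 1 of 50 genes changed 2-fold, 21 of 50 changed 4-fold, 43 of 50 changed 8-fold and 47 of 50 changed 16-fold. Of its 120 calls 8 were false. In a second simulation with the amino acid transporter list raised 2-fold, that list was called and 0 others. Genes were drawn independently there, so it cannot show how often camera calls lists of correlated genes in the real libraries.

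Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 44 lists of at least 3 tested members. A 45th list, mitochondrially encoded genes, matched 0 symbols and was not analysed here. The lists cover Yap and Hippo genes, glutamine, amino acid transport and nucleotide metabolism, replication and mitosis, protein synthesis and stress responses, liver metabolism and secretion, immune responses, and markers of the other cell types and neighbouring organs that a dissected liver could hold. Of the 44 lists 6 were called, 4 higher and 2 lower; with a correlation estimated from the data 0 were called (2 at an unadjusted p under 0.05), and with fry 0 were called in its directional test (6 at an unadjusted p under 0.05) and 20 in its mixed test. The median, the mean and the direction of the test differed in sign for the lists of gluconeogenesis, glutamine, deoxynucleotides, glycolysis, bile acids, amino acid breakdown, complement, erythrocytes, intestine and cholangiocytes.

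The genes named were chosen by a rule set before the data were examined. Part 1 was a fixed set of 15 genes around Yap, glutamine, nucleotides and liver identity, 3 of which, the glutamine synthetase genes, had no matching symbol. Part 2 took the 6 largest increases and 6 largest decreases among genes that passed, with a mean of at least 5 CPM in the higher group, no overlap of the groups and a symbol that is no clone name. Part 3 took up to 3 members that passed from each called list and 1 from each other list. As written, part 2 left out every symbol that begins with a capital, which removed the human-style symbols as well, so 12 such genes were added by the same ranking after their values were seen. In all 39 genes were taken, of which 31 passed.

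Alternatives set before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with and without sample quality weights, no filter and a stricter filter (5 CPM in 3 libraries), library sizes without the 20 most abundant genes, the replicate number as a block, a fold threshold, and each library left out in turn. A pancreas score as covariate and the removal of genes that share reads were added later. Genes sharing reads were sought as genes with counts within 2% of each other in all libraries and at least 100 reads in each. There were 41 such genes in 20 clusters, 22 pairs against 0 after shuffling. They are called genes sharing reads here, though whether they do was not tested. Checks on gene order and the tables used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots matplotlib 3.10.9.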

Results

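Polyadenylated RNA from adult zebrafish liver was sequenced in 6 libraries, 3 from wild-type (WT) fish and 3 from fish of a transgenic line labelled lf:Yap. Yap, encoded by yap1, is a transcriptional coactivator that the Hippo kinase cascade keeps in check, and the series asks how it acts on glutamine metabolism and nucleotide synthesis in the liver. The WT libraries held 71581315, 87543545 and 84761179 gene counts and the lf:Yap libraries 85208212, 76038709 and 76817582. Of 25640 genes in the table, 24486 had at least 1 read in every library. The 20 most abundant genes took 25.3% to 28.7% of the counts of a library. In a principal component analysis of log2 CPM the first component, with 30% of the variance, separated the groups.

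The lf:Yap livers carried far more yap1 transcript than the WT livers, together with several genes known as direct outputs of Yap. YAP1 (ENSDARG00000068401) stood at 22.6, 27.4 and 20.4 CPM in the WT libraries and at 443, 386 and 291 CPM in the lf:Yap libraries. This was a 15.9-fold increase (log2 fold change 3.99 ± 0.25, SE; adjusted p = 0.00663 by edgeR's quasi-likelihood test), which matches the direction of the labels; reads of a transgene with zebrafish yap1 sequence would be counted at the same gene. The related coactivator gene WWTR1 (ENSDARG00000067719), which encodes Taz, averaged 14.8 ± 1.14 CPM in WT and 14.3 ± 2.22 CPM in lf:Yap (SD, n = 3 each), a log2 difference of -0.04 ± 0.20 (SE). Among 26 tested members of the Yap/Taz target list, 3 rose and 0 fell with adjustment over all genes, and 6 rose and 0 fell when adjusted over the list alone (9 higher and 1 lower at an unadjusted p under 0.05 by edgeR, 6 higher and 1 lower by DESeq2, 3 higher by limma-voom). amotl2b (ENSDARG00000061948), which encodes an angiomotin-like protein that binds Yap, rose 20.8-fold from 6.87 ± 2.88 to 142.9 ± 18.5 CPM (SD, n = 3 each). CCN2 (ENSDARG00000042934), the connective tissue growth factor gene, rose 15.8-fold to 36 ± 10.9 CPM. LATS2 (ENSDARG00000078864), a kinase that inhibits Yap, rose 2.60-fold to 56.1 ± 7.72 CPM. Their edgeR adjusted p-values were 0.00924, 0.0172 and 0.0362. Other target genes did not pass: CCN1 (ENSDARG00000023062) differed by 0.63 ± 0.34 (log2, SE; adjusted p = 0.569, edgeR) and ANKRD1 (ENSDARG00000076192), at 0.194 CPM in WT, by -0.50 ± 0.61 (adjusted p = 0.845, edgeR). The target list as a whole was higher by limma's camera test (median log2 fold change 0.40, 0.281 to 0.587 without 1 library and 0.925 over the members left by a filter of 5 CPM in 3 libraries; 18 of 26 members above 0, adjusted p = 1.58e-05; adjusted p = 0.72 with an estimated correlation). Of 23 tested genes in the list of Hippo pathway and Tead genes, which left LATS2 and amotl2b to the target list, YAP1 itself rose and 22 did not pass (camera adjusted p = 0.0658).

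**Figure D1:**
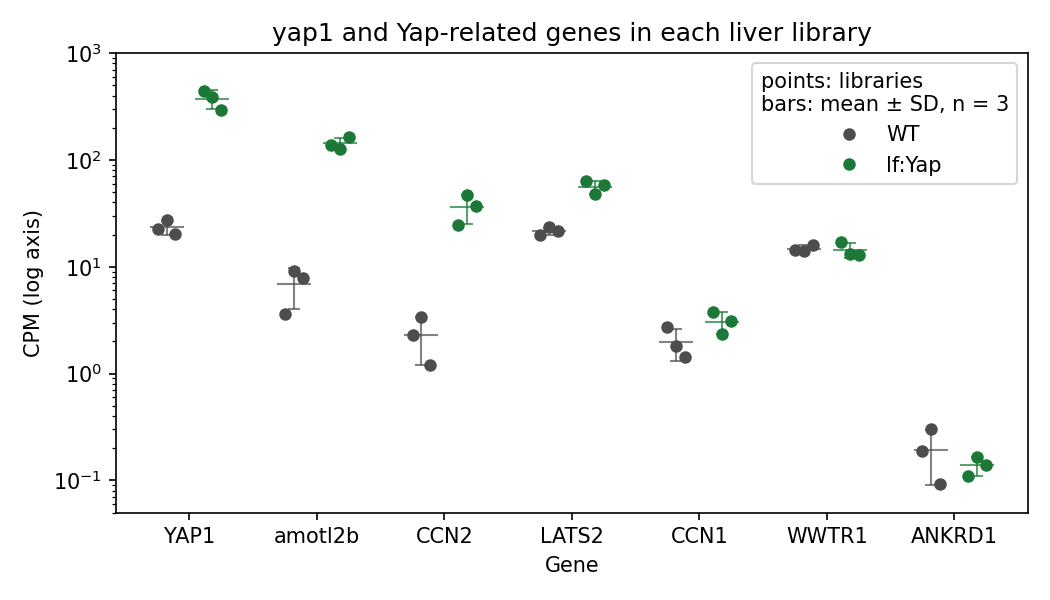
CPM on a log axis of yap1, its relative WWTR1 and 5 target genes in each library, WT in grey and lf:Yap in green, with each group's mean ± SD (n = 3). For YAP1, amotl2b, CCN2 and LATS2 the 3 lf:Yap libraries lie above the 3 WT libraries, whereas CCN1, WWTR1 and ANKRD1 overlap.

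In all, 164 of 24674 tested genes changed, of which 137 were higher and 27 lower in lf:Yap (edgeR, adjusted p under 0.05). The smallest change among them was 1.29 on the log2 scale, and the groups did not overlap for any of the 164; over all tested genes 17.6% had groups without overlap, against 10% by chance for 3 against 3 libraries. Among genes that passed at a mean of at least 5 CPM in the higher group, with zebrafish-style symbols that are no clone names, the largest increases were those of slitrk3b (ENSDARG00000074739), a neuronal transmembrane protein gene, by 6.06 ± 0.89 (log2, SE), and of amotl2b. lifrb (ENSDARG00000039863), a receptor of the leukemia inhibitory factor family, rose by 3.62 ± 0.46. The kinase gene snrkb (ENSDARG00000017665) rose by 3.61 ± 0.36. The small GTPase gene arl5c (ENSDARG00000035719) rose from 17.5 ± 5.76 to 204.7 ± 20 CPM (SD, n = 3 each), and the transcription factor gene atoh8 (ENSDARG00000037555) from 3.05 ± 1.71 to 32.9 ± 11.9 CPM. The largest decrease among these genes was that of cfap70 (ENSDARG00000058508), a gene for a cilia and flagella associated protein, from 56.8 ± 14.3 to 0.908 ± 0.497 CPM (log2 fold change -5.97 ± 0.49, SE; adjusted p = 0.00793, edgeR). tac4 (ENSDARG00000096234), a tachykinin gene, had a log2 fold change of -5.23 ± 0.82 and aqp9b (ENSDARG00000053480), an aquaglyceroporin gene, one of -4.89 ± 0.62. ppp2r3b (ENSDARG00000076004), a regulatory subunit of protein phosphatase 2A, went from 33.3 ± 7.09 to 2.23 ± 0.786 CPM. nfe2l2b (ENSDARG00000089697), a paralog of the oxidative stress regulator Nrf2, had a log2 fold change of -3.66 ± 0.40, and pimr170 (ENSDARG00000074873), of a Pim-related kinase family, one of -3.42 ± 0.46.

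Genes that carry human-style capital symbols in the name table include larger changes, and those named here were chosen after their values were seen. CCN5 (ENSDARG00000077882), a relative of CCN2, rose from 0.177 ± 0.119 to 31.2 ± 19.9 CPM (SD, n = 3 each; log2 fold change 7.44 ± 0.71, SE). CRYAA (ENSDARG00000053502), an alpha-crystallin chaperone gene, rose by 6.43 ± 0.61 on the log2 scale. IYD (ENSDARG00000076056), an iodotyrosine deiodinase gene, rose by 5.28 ± 0.64, and FAT2 (ENSDARG00000018923), an atypical cadherin gene, by 4.43 ± 0.58. FKBP5 (ENSDARG00000028396), a co-chaperone of steroid receptors, rose 19.1-fold to 1395 ± 117.2 CPM. SAT1 (ENSDARG00000032272), the polyamine-acetylating enzyme gene, rose 18.2-fold to 37.1 ± 1.80 CPM. Among the decreases, SNX10 (ENSDARG00000004405), a sorting nexin gene, had a log2 fold change of -4.63 ± 0.61 and MDGA2 (ENSDARG00000024017), a cell adhesion gene, one of -3.26 ± 0.37. BHLHE40 (ENSDARG00000004060), a circadian and hypoxia-linked repressor gene, went from 182.0 ± 73.4 to 27.7 ± 11.4 CPM. FLRT3 (ENSDARG00000076895), TBX2 (ENSDARG00000006120) and FZD5 (ENSDARG00000025420), the last a Wnt receptor gene, had log2 fold changes of -2.06, -2.02 and -1.79. All these named changes passed edgeR's test at adjusted p-values between 0.00712 and 0.0493. Of the 31 named genes that passed, 7 also passed in each of the 6 fits that left out 1 library, namely YAP1, arl5c, cfap70, ppp2r3b, LPIN1, CRYAA and SAT1; 17 passed in some of those fits and 7 in none of them, among the latter LATS2 and atoh8, and each kept its direction. The number of changed genes itself was 94, 41 and 32 without WT replicates 1, 2 and 3, 48, 84 and 66 without lf:Yap replicates 1, 2 and 3, and 1063 by DESeq2 with all libraries.

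Amino acid transporter genes leaned upward, while the enzymes of glutamine metabolism and of nucleotide synthesis showed no change that passed the test over all genes. Of 26 transporter genes tested 0 passed over all genes, against 9 higher and 1 lower at an unadjusted p under 0.05 by edgeR, 7 higher and 1 lower by DESeq2 and 0 by limma-voom; 7 were higher and 1 lower when adjusted over the list alone. The list was higher by camera (median log2 fold change 0.92, 19 of 26 members above 0, adjusted p = 3.86e-05; adjusted p = 0.72 with an estimated correlation). Its median was 0.485 without lf:Yap replicate 3, 0.549 without lf:Yap replicate 1 and up to 0.997 in the other fits that left out 1 library. The following 3 examples were chosen after their values were seen. SLC3A2 (ENSDARG00000037012), the heavy chain shared by several transporters, averaged 2.43 ± 1.21 CPM in WT and 25.9 ± 14.9 CPM in lf:Yap (SD, n = 3 each; adjusted p = 0.059 over all genes and 0.0119 over the list alone, edgeR). SLC38A4 (ENSDARG00000018149), a neutral amino acid carrier of hepatocytes, averaged 1370 ± 399 and 4554 ± 1965 CPM (adjusted p = 0.107 and 0.0198, edgeR). The exception in direction was SLC38A3 (ENSDARG00000091061), a glutamine carrier, with a log2 fold change of -0.95 ± 0.26 (SE; adjusted p = 0.221 and 0.0298, edgeR).

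None of the 22 tested genes of glutamine and glutamate metabolism passed over all genes, with 3 higher and 1 lower at an unadjusted p under 0.05 (edgeR), 1 higher by DESeq2 and 0 by limma-voom. Of these genes 8 lay above 0 and 14 below. The list's median was -0.15 and its mean 0.13, so that they differed in sign, and camera gave an adjusted p of 0.962. The median itself was 0.125 without WT replicate 3, 0.0189 without lf:Yap replicate 3 and down to -0.202 in the other fits that left out 1 library. Chosen after its values were seen, prodha (ENSDARG00000086746), a proline dehydrogenase gene, differed by 2.93 ± 0.64 (log2, SE; adjusted p = 0.134, edgeR). The glutamine synthetase genes glula, glulb and glulc were not analysed here. Among 12 genes of de novo purine synthesis 0 passed over all genes and 1 was lower when adjusted over the list alone (2 lower at an unadjusted p under 0.05 by edgeR, 1 lower by DESeq2, 0 by limma-voom; camera adjusted p = 0.154, median -0.20, and -0.222 to -0.0802 without 1 library). That gene was PAICS (ENSDARG00000033539), with 15.7 ± 2.97 CPM in WT and 6.87 ± 1.01 CPM in lf:Yap. PPAT (ENSDARG00000004517), which encodes the amidotransferase that commits to the purine pathway, differed by -0.95 ± 0.30 (log2, SE; adjusted p = 0.286, edgeR). Among 6 genes of de novo pyrimidine synthesis 0 passed (1 lower at an unadjusted p under 0.05 by edgeR, 0 by DESeq2 and by limma-voom; camera adjusted p = 0.448, median -0.23, and -0.448 to 0.0148 without 1 library). CAD (ENSDARG00000041895), whose product carries out the first steps of that pathway, read 97.3, 149.3 and 377.8 CPM in the WT libraries and 78.3, 81.4 and 97.7 CPM in the lf:Yap libraries (log2 fold change -1.28 ± 0.48, SE; adjusted p = 0.376, edgeR). Leaving out WT replicate 3, the highest, gave the CAD difference nearest to 0, -0.53. Of 12 genes of deoxynucleotide synthesis 0 passed (1 higher at an unadjusted p under 0.05 by edgeR, 0 by DESeq2 and by limma-voom), with a median of 0.018 (-0.113 to 0.146 without 1 library), a mean of -0.044 and a camera adjusted p of 0.962. SLC2A1 (ENSDARG00000007412), a glucose transporter gene, averaged 3.47 ± 1.58 CPM in WT and 12 ± 7.47 CPM in lf:Yap (adjusted p = 0.257 by edgeR and 0.0246 by DESeq2, and up to 0.593 among the fits that left out 1 library).

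**Figure D2:**
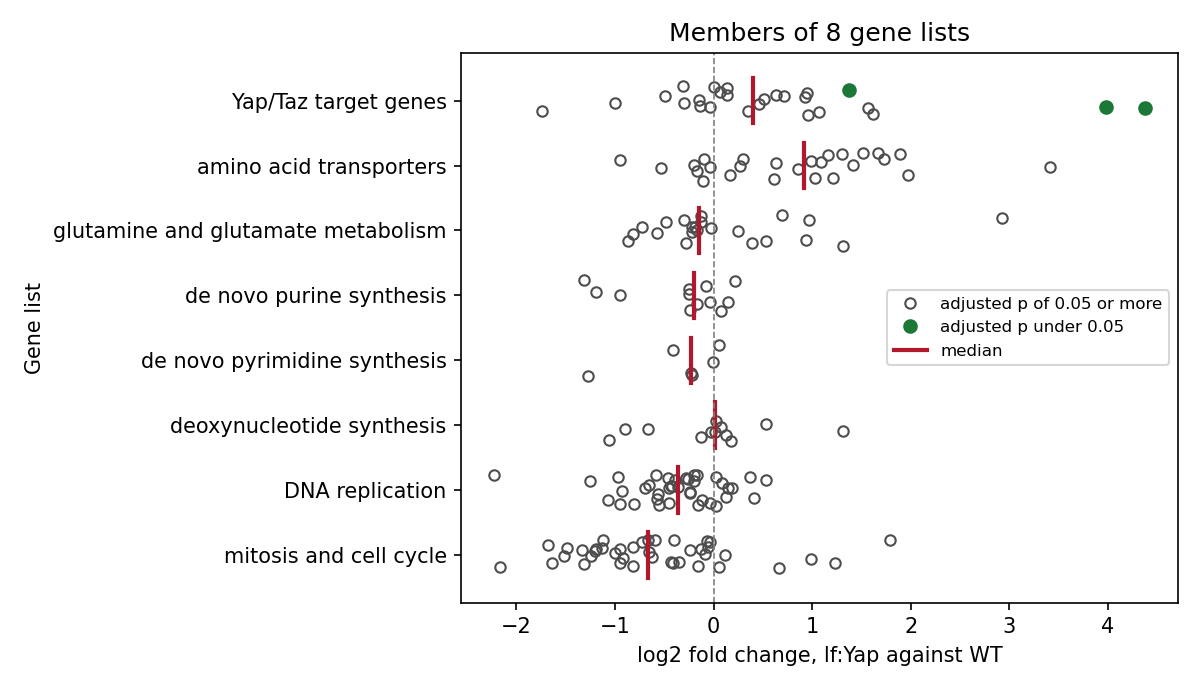
Each point is the log2 fold change, lf:Yap against WT, of 1 tested member of the gene list on its row; filled points passed edgeR's test over all genes and the red line is the list's median. Medians run from -0.66 for mitosis and cell cycle to 0.92 for amino acid transporters, and the 3 filled points belong to the Yap/Taz targets.

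Cell division genes leaned downward in the lf:Yap livers by camera at its preset correlation, but not past the threshold with an estimated correlation, and no single one of them passed. In the mitosis and cell cycle list 34 of 40 tested genes lay below 0, with a median log2 fold change of -0.66 (camera adjusted p = 0.00385; adjusted p = 0.924 with an estimated correlation). In the DNA replication list 30 of 39 lay below 0, with a median of -0.36 (camera adjusted p = 0.048; adjusted p = 0.72 with an estimated correlation). By edgeR 0 members of either list passed over all genes or adjusted over the list alone; at an unadjusted p under 0.05 there were 7 lower and 1 higher in the first list and 4 lower and 0 higher in the second, DESeq2 called 1 lower and 0 lower, and limma-voom 0 in both. Chosen after their values were seen, the mitotic kinase gene plk1 (ENSDARG00000058471) averaged 1.55 ± 0.392 CPM in WT and 0.621 ± 0.190 CPM in lf:Yap (SD, n = 3 each), and MCM10 (ENSDARG00000045815), a replication initiation factor gene, 1.07 ± 0.764 and 0.227 ± 0.0403 CPM. Macrophage marker genes lay in the same direction, with 24 of 28 below 0 and a median of -0.39 (camera adjusted p = 0.0784), but 0.0989 without WT replicate 1. The mitosis list's adjusted p was 0.0906 without WT replicate 1, where its median was -0.341, and that of DNA replication was 0.122 without WT replicate 1, 0.053 without WT replicate 3 and 0.167 without lf:Yap replicate 3. Across the 10 ways of parting the 6 libraries into groups of 3, camera with its preset correlation called 6 lists for the real groups and 7 to 22 for the others, so that its calls were no more frequent for genotype than for other partings.

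Camera called 2 further lists, both higher in lf:Yap and both with an adjusted p of 0.048 (adjusted p = 0.72 with an estimated correlation). In the gluconeogenesis and glycogen list the mean was 0.47 but the median -0.085, with 9 of 19 members above 0 (median 0.104 to 0.285 without 1 library); 0 members passed over all genes (4 higher at an unadjusted p under 0.05 by edgeR, 4 higher by DESeq2, 1 higher by limma-voom) and 3 were higher when adjusted over the list alone. Those 3 genes were PPP1R3C (ENSDARG00000071005), a glycogen-targeting phosphatase subunit, at 115.6 ± 50.3 CPM in WT and 734.8 ± 232.2 CPM in lf:Yap (SD, n = 3 each), and the glucose-6-phosphatase genes G6PC1 (ENSDARG00000013721) and g6pc1a.1 (ENSDARG00000031616), with log2 differences of 1.92 ± 0.35 and 1.59 ± 0.34 (SE). Another ID with the symbol PPP1R3C (ENSDARG00000014554) leaned the other way. It averaged 69.95 CPM in WT and 49.2 CPM in lf:Yap, a log2 difference of -0.51 ± 0.29 (SE; adjusted p = 0.594, edgeR). Without 1 library this list's adjusted p was 0.0822 (WT replicate 1), 0.0947 (WT replicate 3) and 0.0864 (lf:Yap replicate 2). In the cytochrome P450 and xenobiotic list 20 of 27 members lay above 0 with a median of 0.27; 0 passed over all genes or adjusted over the list alone (5 higher at an unadjusted p under 0.05 by edgeR, 2 higher by DESeq2, 0 by limma-voom). The members with the lowest p were sulfotransferase genes and not P450 genes, such as sult1st1 (ENSDARG00000028275), with a log2 difference of 2.17 ± 0.51 (SE). Its adjusted p was 0.0822 without WT replicate 1, 0.0501 without WT replicate 2 and 0.222 without lf:Yap replicate 1.

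In the other lists named here, the single members that passed over all genes rose. ldlra (ENSDARG00000029476), the low density lipoprotein receptor gene, rose 10.5-fold from 177.7 ± 84.7 to 1864 ± 219.6 CPM (SD, n = 3 each; adjusted p = 0.0144, edgeR), as the only one of 20 genes of cholesterol synthesis and uptake to pass (camera adjusted p = 0.0786). LPIN1 (ENSDARG00000020239), a phosphatidate phosphatase gene, rose 7.77-fold from 76.4 ± 5.24 to 593.8 ± 145.6 CPM among 22 fatty acid synthesis genes (camera adjusted p = 0.315). nfkbiab (ENSDARG00000007693), an inhibitor of NF-kappa-B, rose 7.12-fold among 18 inflammation genes (camera adjusted p = 0.348; 2 higher and 1 lower by DESeq2). In that list cxcl18b (ENSDARG00000075045) averaged 25.3 ± 5.44 CPM in WT and 6.62 ± 2.78 CPM in lf:Yap (adjusted p = 0.0921 over all genes and 0.0101 over the list alone, edgeR). SOCS1 (ENSDARG00000038095) averaged 2.91 ± 2.06 and 23.3 ± 17.4 CPM (adjusted p = 0.213 and 0.0441, edgeR). ENO1 (ENSDARG00000022456), 1 of the enolase genes, rose 3.50-fold among 24 glycolysis genes (camera adjusted p = 0.695). Of these genes DESeq2 called 2 higher and 2 lower. LDHB (ENSDARG00000019644), a lactate dehydrogenase gene, averaged 223 ± 16.4 CPM in WT and 58.6 ± 29.7 CPM in lf:Yap (adjusted p = 0.0907 over all genes and 0.0129 over the list alone, edgeR). In the list of the unfolded protein and ATF4 response 0 of 32 passed over all genes (5 higher and 2 lower at an unadjusted p under 0.05 by edgeR, 5 higher and 1 lower by DESeq2, 1 higher by limma-voom), and 4 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.126). CHAC1 (ENSDARG00000070426), a glutathione-degrading ATF4 target chosen after its values were seen, averaged 105.9 ± 68.5 CPM in WT and 1358 ± 229.9 CPM in lf:Yap (adjusted p = 0.0506, edgeR).

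Hepatocyte genes showed no change as a group that passed the test. The hepatocyte secreted protein genes took 18.1% to 21.9% of counts in WT and 19.6% to 21.0% in lf:Yap, with a median log2 fold change of 0.04 over 47 genes (camera adjusted p = 0.448). Of these genes 0 passed edgeR's test over all genes (8 higher and 1 lower at an unadjusted p under 0.05, 3 higher by DESeq2, 0 by limma-voom). fabp10a (ENSDARG00000038439), the liver fatty acid binding protein gene, averaged 8770 ± 691.9 CPM in WT and 13199 ± 1707 CPM in lf:Yap (adjusted p = 0.232, edgeR). The egg yolk precursor gene vtg1 (ENSDARG00000092233), which estrogen raises in female liver, was at 0.917 ± 1.09 and 1.5 ± 1.07 CPM, and the 8 estrogen-responsive genes gave a camera adjusted p of 0.0741. Digestive enzyme genes of the exocrine pancreas differed between libraries but not by group: they took 2.72%, 0.141% and 0.264% of counts in the WT libraries and 1.88%, 0.0495% and 2.60% in the lf:Yap libraries (camera adjusted p = 0.401). The 29 such genes at a mean of 1 CPM or more rose and fell together, with a median pairwise Pearson correlation of 0.982 across the libraries. A fit with a pancreas score as covariate, added after seeing the data, called 129 genes, 116 of them among the 164.

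**Figure D3:**
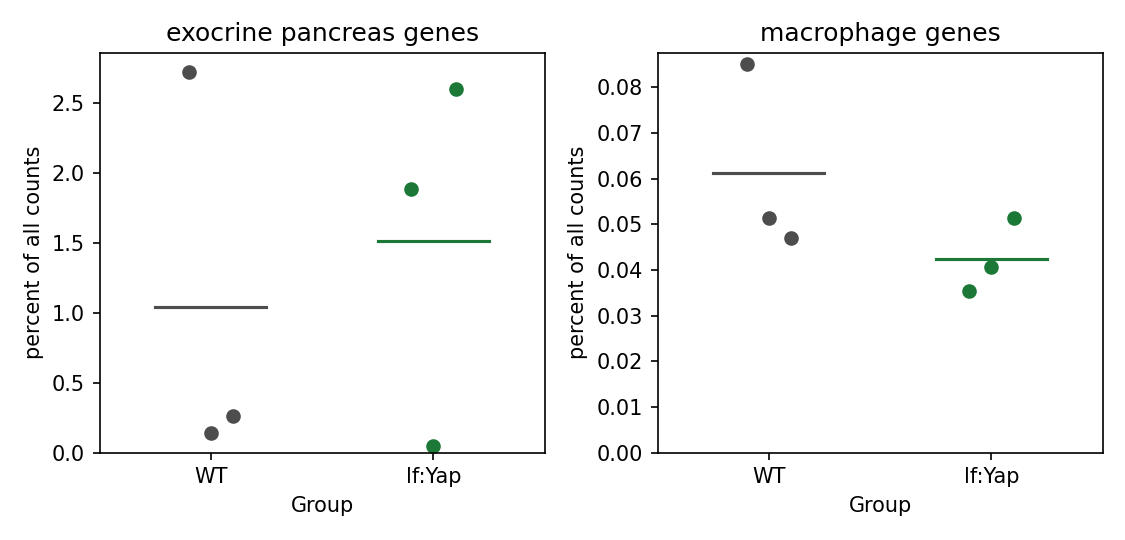
Percent of all gene counts taken by exocrine pancreas marker genes (left) and macrophage marker genes (right) in each library, with a line at each group's mean. Pancreas genes reach 2.72% in 1 WT library and 2.60% in 1 lf:Yap library; macrophage genes lie between 0.0353% and 0.085%.

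No other list passed camera's test. Camera adjusted p-values of the remaining cell type lists were 0.985 for cholangiocyte and progenitor genes, 0.348 for stellate and fibroblast genes, 0.323 for endothelial, 0.962 for erythrocyte, 0.401 for neutrophil and 0.913 for lymphocyte genes. They were 0.62 for pancreatic islet, 0.962 for intestine, 0.33 for gonad and germ cell and 0.0741 for kidney genes. For protein synthesis and turnover they were 0.124 for ribosomal proteins (median 0.11, 65 of 69 above 0), 0.149 for ribosome biogenesis (median -0.47, 40 of 45 below 0, but a median of 0.229 without WT replicate 3), 0.695 for aminoacyl-tRNA synthetases (median -0.328, and 0.431 without WT replicate 3) and 0.323 for the proteasome. For metabolism they were 0.39 for serine and one-carbon metabolism, 0.913 for Nrf2 antioxidant genes, 0.62 for bile acid synthesis and transport, 0.281 for fatty acid oxidation, 0.962 for nuclear oxidative phosphorylation genes and 0.962 for amino acid breakdown and the urea cycle. For the lists left they were 0.983 for complement and acute phase and 0.269 for extracellular matrix and fibrosis. They were 0.0531 for the interferon response (median -0.32, and -0.63 to -0.159 without 1 library) and 0.195 for immediate early and heat shock genes. In these lists 1 member passed over all genes, CCN2 among the stellate and fibroblast genes. Some intestine genes were high in a single library. SLC15A1 (ENSDARG00000044528) read 49.1 CPM in lf:Yap replicate 1 and at most 0.444 CPM elsewhere, and VIL1 (ENSDARG00000040466) 26.8 and at most 2.66 CPM. FABP6 (ENSDARG00000044566) read 45.6 CPM in WT replicate 2 and at most 0.504 CPM elsewhere. Whether intestine was carried over into these livers was not tested.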

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

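The pancreas covariate and the removal of genes sharing reads were chosen after seeing the data; all other settings were set before. The 164 changed genes (137 higher, 27 lower) stayed within 1.5 times under RLE and upper-quartile factors, limma-voom, both filters, library sizes without the most abundant genes, a fold threshold, the pancreas covariate and 1 gene per cluster of shared reads, between 129 and 206 genes counting voom with quality weights, which called 41 lower. No called gene reversed in any setting. DESeq2 called 1063 genes, 673 higher and 390 lower, among them all 164 (131 genes had no adjusted p); the cause was not tested. Leaving out 1 library gave 32 to 94 genes, 27 to 72 higher and 5 to 22 lower, with fewer samples in each fit. With the replicate block the counts were 17, 14 and 3, of which 16 were among the 164. Same-numbered libraries correlated at 0.077, 0.0307 and -0.212 in their deviations from the group means, and libraries did not all correlate best with their own number. These values show no pairing by number, but so few cannot exclude that same-numbered livers were handled together. Gene list tests called 6 lists, 2 under the stricter filter with fewer genes tested (Yap/Taz targets and amino acid transporters; DNA replication at an adjusted p of 0.572, gluconeogenesis and cytochrome P450 at 0.23, mitosis not tested with 1 member left), 5 to 11 without 1 library, 0 with an estimated correlation, 0 by directional fry and 20 by mixed fry. Aminoacyl-tRNA synthetases turned to higher without WT replicate 3 (camera adjusted p = 0.0145, median 0.431 against -0.328 with all libraries); over the fits without 1 library their adjusted p ran from 0.0145 to 0.983, and the cause was not tested. Over all settings, single named genes kept their direction and side of the threshold in 514 comparisons, lost the call in 143 and gained it in 1; lists did so in 582, 26 and 46, and 1 reversed. The planned corrections for GC content and length and the test by chromosome were not run, since no annotation of the counted genes was used here. At this depth and spread, simulation recovered 1 of 50 2-fold changes, 21 of 50 4-fold changes and 43 of 50 8-fold changes. A gene not called may therefore still differ by 2-fold or 4-fold, and less often by 8-fold.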

Other observations

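The tests of neutrophils and lymphocytes, of macrophages, of fasting and with the pancreas covariate were chosen after the data were seen, as were the checks on corticoid-responsive, fasting-raised and clock genes without the members seen first; the 5 added gene lists were composed, and the remaining tests written, after a first look at the 40 leading genes and the tests of the 44 lists. That look had shown KLF9, HSD11B2, LPIN1, nr1d2a and usp2b, which are members of 3 of the added lists. Several genes known to respond to corticoid hormones were higher in the lf:Yap livers. KLF9 (ENSDARG00000068194) averaged 31.7 CPM in WT and 233.5 CPM in lf:Yap, HSD11B2 (ENSDARG00000001975), which inactivates cortisol, 170.2 and 863.7 CPM, and FKBP5 73.0 and 1395 CPM. Of 17 such genes 14 lay above 0 and 3 passed edgeR's test (median log2 fold change 0.93; camera adjusted p over the 5 added lists 3.94e-11, and 0.0268 with an estimated correlation). Without KLF9 and HSD11B2 the other 15 members had a median of 0.89 ± 0.35 (SE), 12 above 0, with a camera adjusted p over the 3 lists so reduced of 5.01e-06, and of 0.0736 with an estimated correlation. Genes that fasting raises in liver also leaned upward, 15 of 20 above 0 with a median of 0.81 (camera adjusted p = 1.07e-06, and 0.0264 with an estimated correlation). Without LPIN1 and the 3 members in the gluconeogenesis list, already called in that look, the other 16 had a median of 0.494 ± 0.356 (SE). That median ran from 0.323 to 0.954 without 1 library. Of these 16 genes 11 lay above 0 and 0 passed the test, with a camera adjusted p of 0.00439, and of 0.0736 with an estimated correlation. In the whole list PCK1 (ENSDARG00000013522), the gluconeogenic carboxykinase gene, averaged 392.5 ± 374.5 CPM in WT and 2173 ± 1286 CPM in lf:Yap (SD, n = 3 each; adjusted p = 0.313, edgeR), while ANGPTL4 (ENSDARG00000035859), an inhibitor of lipoprotein lipase, went the other way, from 62.9 ± 65.6 to 6.57 ± 1.95 CPM (adjusted p = 0.18, edgeR).

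Some regulators of the circadian clock changed, but not together. nr1d2a (ENSDARG00000003820) rose from 36.1 to 249.7 CPM and usp2b (ENSDARG00000074120) from 8.73 to 38.62 CPM, while BHLHE40 and nr1d4b (ENSDARG00000059370) fell, the latter with a log2 fold change of -2.68. Of 17 clock genes on the nr1d and per side, 8 lay above 0 and 9 below (median -0.059, camera adjusted p = 0.0654). Without nr1d2a and usp2b, 6 of the other 15 lay above 0 and 0 were called higher (median -0.114 ± 0.341, SE; camera adjusted p = 0.676). Other genes that passed, chosen after their values were seen, included MYL9 (ENSDARG00000008030), a myosin light chain gene, at 36.2 and 280.4 CPM, MYLK (ENSDARG00000034801), the kinase of that light chain, at 11.5 and 28.9 CPM, TGFBR2 (ENSDARG00000034541) at 15.98 and 95.4 CPM, VEGFC (ENSDARG00000069640) at 1.99 and 13.2 CPM and DIO2 (ENSDARG00000094857), a thyroid hormone activating enzyme gene, at 423.7 and 1638 CPM in WT and lf:Yap.

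The corticoid, fasting and clock genes may have differed because of how the fish were kept or collected. A collection at another time of day would set the nr1d and per side against the bmal and clock side; the latter had a median of 0.407 ± 0.281 (SE), which decides neither way. Fasting would lower feeding-raised genes, whose median was 0.0426 ± 0.475, also undecided; the only one of them that passed, ldlra, rose 10.5-fold, against that direction. For the 15 corticoid-responsive genes not seen beforehand, the lowest median without 1 library was 0.644 ± 0.294. Each such fit gave a median above 0 by more than 2 standard errors except that without lf:Yap replicate 3, at 0.727 ± 0.436. In other partings of the libraries their absolute median reached 0.515 at most, against 0.893 in the real one. That comparison decides nothing, since the list was composed after KLF9 and HSD11B2 were seen among the leading genes of the real groups. Genes that follow those 2 would favour the real parting, and 10 partings are too few for a share under 0.05. Handling, feeding, time of collection and the lf:Yap genotype itself cannot be told apart here, since the labels give no times or feeding and each would follow the groups.

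The medians of mitosis and DNA replication genes stayed below 0 in each fit without 1 library, at -0.341 ± 0.105 and -0.249 ± 0.0803 (SE over genes) or lower. An SE over genes does not measure the spread between livers. With all libraries the medians were -0.665 and -0.36, and the camera calls were lost in 1 and 3 of the 6 fits. The direction of the medians thus did not rest on 1 library, though part of their size did. Differing amounts of pancreas leave them below 0, with medians of -0.636 ± 0.165 and -0.29 ± 0.101 once a pancreas score is in the fit. A loss of neutrophils and lymphocytes would need their genes to be at least as low, and the lower of their medians was 0.129 ± 0.213. The lymphocyte median lay above the mitosis median in each fit without 1 library (-0.318 to 0.543). The neutrophil median ran from -0.602 to 0.713 over these fits. Its low end lay near the mitosis median with all libraries, so a loss of neutrophils stays undecided. Only 4 neutrophil and 2 lymphocyte members were left by a filter of 5 CPM in 3 libraries. The same filter left 1 mitosis and 6 DNA replication members, so the division medians too rest mostly on genes of low count. Fewer macrophages, with a median of -0.394 ± 0.0886, could account for part of the difference, although the share of counts of macrophage genes overlapped between the groups (0.047% to 0.085% in WT, 0.0353% to 0.0513% in lf:Yap); without WT replicate 1 the macrophage median was 0.0989 while both division medians stayed below 0. How much macrophages account for was not tested, and an effect of genotype on division stays open as a hypothesis.

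A chromosome segment that differs between the lines could also change neighbouring genes by large folds. Of the 164 genes only 82 (50%) could be placed by symbol, under the 80% needed, so the check is void; for the record, 2 of them had another changed gene among the 5 nearest tested genes on either side, against a median of 4 over 10000 random draws.

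The 6 libraries can be parted into 2 groups of 3 in 10 ways, too few for a share under 0.05. Of these, 1, the real one, gave as many as 164 changed genes, and the highest other gave 3. For gene lists all 10 gave at least the 6 calls of the real groups, and the highest other gave 22, several times the real count, which points to structure among the libraries that does not follow genotype. With an estimated correlation each of the 10 partings called 0 lists by camera.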
